A study of Arabidopsis thaliana with 14 samples.

How the data were processed

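Total RNA of whole Arabidopsis thaliana seedlings was measured on 14 single-colour Agilent arrays. Per the labels, wild-type Col-0 seedlings and seedlings carrying 35S:YFP-AFL1 were grown for 7 days on agar plates and then moved to fresh control plates or to plates infused with polyethylene glycol at a water potential of -1.2 MPa, and were harvested 10 h after the transfer. The samples formed 4 groups of genotype and treatment, with 4 wild-type arrays and 3 35S:YFP-AFL1 arrays in each treatment. The labels do not say whether the replicates came from separate cultures, so that p-values measure only the spread between these samples, which may be technical.

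Per the file headers, the authors' spot intensity values came from Agilent Feature Extraction 10.7.1.1, which subtracts the background within each array and writes a processed signal on a linear scale. The deposited table of all samples held these same intensity values, with a largest relative difference of 6e-04 from the scanner files, so that it carried no normalization between arrays. The scale of that table was linear with no centring, and the medians of its columns ran from 152.5 to 320.5. The values of 1 array, 35S:YFP-AFL1 at low water potential replicate 1, were written with 3 significant digits. Each file held 45220 spots, of which 43803 were not controls, and these belonged to 43603 probes. The accession of a probe was matched without its version to the transcripts of the TAIR10.1 gene table, which was used for names and for which genes neighbour each other. The match gave a gene for 34358 probes (78.8%) and none for 9245 probes (21.2%), and 25433 genes had a probe. Gene start positions from the gene table served to find the measured genes nearest to WRKY13. No probe coordinates were used, because the array design carries an older build label.

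The main values were log2 of the processed signal minus the array's 75th percentile of it, over spots that were not controls. Spots marked as outliers by Feature Extraction were left out where another spot of the probe remained, and the spots of a probe were averaged. A probe was kept if it was well above background on at least 3 arrays of at least 1 group, which 29098 probes were. The probe with the highest mean signal stood for a gene, which gave 18307 genes tested, of which 8249 had a gene symbol. Of the 5670 genes with several such probes, 42 had probes called in opposite directions for the stress response of wild type and 36 for that of 35S:YFP-AFL1. The 75th percentile of the signal ran from 796.2 to 1591 over the arrays, between 59.62% and 67.11% of the probes were well above background, and 0 spots were saturated. The number of arrays limits the precision.

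Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) in a single fit of 4 group means to all 14 arrays, with 10 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and every adjusted p given for a gene is from this fit unless said otherwise. The 5 comparisons were the stress response in each genotype, the genotype difference in each treatment, and the difference of the stress responses. A further 28 gene lists with 532 genes, of which 484 were tested, were written from textbook knowledge before the data were examined, as were the comparisons, the thresholds and the rule for naming genes. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 28 lists of a comparison, and again with the correlation estimated from the data. The genes named were AFL1 and its family, the 10 highest and 10 lowest fold changes of a comparison among genes with a symbol, a call and no overlap of the groups' arrays, and up to 4 called members of each list. Genes named outside that rule are said to be so.

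A probe not well above background on any array of a group has only a bound there. Such differences are given as "at least" a fold, from the mean of the brighter group against the mean, per array of the dimmer group, of the lowest signal among probes well above background or the probe's own signal, whichever was higher.

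The file headers also gave the slide and the scan day. Slides 1 and 2 were scanned on scan day 1, and slides 3, 4 and 5, with every 35S:YFP-AFL1 array, on scan day 2. Slide 1 held wild-type control replicates 2 and 3, slide 2 wild-type control replicate 4 with wild-type stress replicate 2, and slide 3 wild-type stress replicates 3 and 4. Slide 4 held the 3 35S:YFP-AFL1 control arrays with wild-type control replicate 1, and slide 5 held the 3 35S:YFP-AFL1 stress arrays with wild-type stress replicate 1. Thus a value with the slide as a block is, for a genotype difference, the value within slide 4 or slide 5 against 1 wild-type array, and for the wild-type stress response it is the value within slide 2. The spread for such a test comes from replicate arrays of the same slide and of other groups and slides, and the lone wild-type array is assumed to vary like them. List tests with the slide as a block used the preset correlation. No slide held 35S:YFP-AFL1 arrays of both treatments, so that their blocked response joins the wild-type response within slide 2 to the differences within slides 4 and 5. The slide was also fitted as a random block (duplicateCorrelation, consensus correlation 0.442), and the scan day as a block.

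Alternatives were normexp background correction with an offset of 50 on median spot and local background signals followed by quantile normalization, quantile normalization and median centring of the processed signal, the deposited table, other filters on dim probes, the mean of a gene's probes, only the groups compared, the replicate number as a block, slide and scan day as blocks, array weights, other thresholds, and leaving out each array. The median spot signal stood in for the mean spot signal, which was not used here. The steps were tested on simulated data made from the real gene means and residual spreads, with 200 genes changed among the 18307. The spread was drawn independently for each gene and array, with no effect of slide or scan day. The shares recovered thus leave out the slide structure, which nearly coincides with genotype, and may be too high for the genotype differences. For the genotype difference in unstressed seedlings, 62% of genes changed by 1 on the log2 scale and 94% of those changed by 2 were recovered. The same shares were 60% and 96% for the genotype difference at low water potential, 66% and 94% for the stress response in wild type, 62% and 90% for that in 35S:YFP-AFL1, and 34% and 76% for the difference of the responses.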

Results

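Gene expression was measured in whole 7-day-old seedlings of wild type (Col-0) and of a line expressing AFL1 (At14a-like 1, AT3G28270), fused to a yellow fluorescent protein, from the 35S promoter. Seedlings were kept on control plates or held at -1.2 MPa for 10 h, with 4 wild-type and 3 35S:YFP-AFL1 arrays per treatment. Arrays of a group correlated at 0.9365 to 0.989 across genes, and no pair of arrays held identical values. The first principal component, which separated the treatments, held 80.5% of the variance. The second component held 8.05% and separated the arrays of slides 4 and 5, which carry all 35S:YFP-AFL1 samples and wild-type replicate 1 of each treatment, from those of slides 1 to 3. Wild-type replicate 1 correlated with the 35S:YFP-AFL1 arrays of its treatment at a mean of 0.977 in control and 0.978 at low water potential, and with the other wild-type arrays at 0.961 and 0.949.

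The first comparison asked which transcripts changed at low water potential in wild type. Lists of abscisic acid (ABA) synthesis, of phosphatases of ABA signalling, of dehydration protection and of heat shock proteins rose, and expansins fell, with calls that held with an estimated inter-gene correlation. Lists of photosynthesis, glucosinolate, cell cycle and auxin response genes fell at the preset correlation, with an adjusted p of 0.149, 0.135, 0.0697 and 0.0653 with an estimated correlation. All 27 measured members of the list of dehydrins, late embryogenesis abundant proteins and dehydration markers rose, with a median log2 fold change of 3.56 and with LEA7 at 8.89, RD20 at 7.82 and COR15A at 7.91. All 9 clade A protein phosphatases 2C, which restrain ABA signalling, rose with a median of 4.43. Among these HAI1 rose by 7.64 ± 0.19 (SE, n = 4 and 4), HAI2 was at least 101-fold higher and HAI3 at least 51.6-fold higher. Of 12 genes of ABA synthesis and catabolism 10 rose and 1 fell (median 1.96), among them NCED3, the stress-induced enzyme that commits carotenoids to ABA, at 6.23 ± 0.23, AAO3 at 3.22 and the ABA hydroxylase gene CYP707A1 at 4.24. In contrast, 8 of 9 ABA receptor genes fell (median -1.38, adjusted p = 0.0697 with an estimated correlation), with PYL4 at -4.39 and PYL5 at -3.52.

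Of 25 drought and ABA transcription factors 16 rose and 1 fell (median 2.58, adjusted p = 0.0843 with an estimated correlation), including HB-7 at 5.48, NAC019 at 5.42 and RD26 at 5.25. Of 12 genes of raffinose and stress sugar metabolism 8 rose and 3 fell (median 2.46, adjusted p = 0.0843 with an estimated correlation), with the sucrose synthase gene SUS3 at 6.66 and ERD6, a sugar transporter, at -4.57. All 16 heat shock protein genes rose (median 4.84), with HSP17.4 at 8.33 and APX2, an ascorbate peroxidase gene on that list, at least 82.4-fold higher. Of 14 genes of senescence and carbon starvation 10 rose and 2 fell (median 2.53, adjusted p = 0.135 with an estimated correlation), with SAG29 at 9.53 and ACD1, which acts in chlorophyll breakdown, at 4.07. Of 15 flavonoid and anthocyanin genes 14 rose and none fell (median 2.15, adjusted p = 0.164 with an estimated correlation), with F3H at 3.76 and the regulator PAP1 at 3.55. Of 25 genes of folding in the endoplasmic reticulum (ER) 14 rose and 1 fell (median 0.54, adjusted p = 0.498 with an estimated correlation), with PDIL1-2 at 1.11 and the chaperone gene BIP1 at 0.91. The 10 proline genes divided into 5 that rose and 4 that fell (median 0.19, adjusted p = 0.365 as a list). P5CS1, the rate-limiting enzyme of proline synthesis, rose by 4.83 ± 0.17 and ERD5, the proline dehydrogenase that degrades it, fell by 2.83. Within scan day 2, which held 1 wild-type control array, P5CS1 changed by 4.97 and ERD5 by -1.316.

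Among genes that fell, all 39 nuclear photosynthesis genes were lower (median -1.65, adjusted p = 0.149 with an estimated correlation), with LHCB3 at -3.33, PSAH2 at -2.99 and PSBQA at -2.92. Of 21 glucosinolate genes 18 fell and 1 rose (median -1.81, adjusted p = 0.135 with an estimated correlation), led by CYP83A1 at -6.95, BCAT4 at -6.87 and MAM1 at -6.14, enzymes of methionine-derived glucosinolates. Of 32 expansin and xyloglucan endotransglucosylase genes, which act in wall loosening, 25 fell and 1 rose (median -1.89), with EXPA8 at -6.04 and XTH9 at -5.23. Of 26 cell cycle and DNA replication genes 23 fell and none rose (median -1.31, adjusted p = 0.0697 with an estimated correlation), with CYCD3;1 at -3.08. Of 17 auxin response genes 14 fell and 1 rose (median -1.53, adjusted p = 0.0653 with an estimated correlation), with ATAUX2-11 at -2.81, and of 12 brassinosteroid and gibberellin genes 8 fell and 1 rose (median -1.07, adjusted p = 0.149 with an estimated correlation), with HBI1 at -5.98. Aquaporins fell in 13 of 18 cases and rose in 1 (median -1.13, adjusted p = 0.0653 with an estimated correlation), with DELTA-TIP at -4.45 and PIP1;5 at -3.30. Of 14 salicylate defence genes 8 fell and 1 rose (median -1.60, adjusted p = 0.194 with an estimated correlation), with PAD4 at -4.03 and EDS1 at -1.96. The median of that list was -1.79 within scan day 1, which held 1 wild-type stress array. It was -0.21 within scan day 2, which held 1 wild-type control array, and its call at the preset correlation was lost there. That control array had a list mean of -1.15, against -0.273 to 0.011 on the other wild-type control arrays. Of 16 genes of ER bodies and associated lectins 11 fell and none rose (median -0.78, adjusted p = 0.194 with an estimated correlation), with JAL33 at -1.53 and NAI2 at -1.44. Shoot epidermis and stomatal lineage markers fell in 7 of 8 cases (median -1.14, adjusted p = 0.0843 with an estimated correlation), with EPF1 at -2.87 and KAT2 at -2.63.

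Among the genes named by the rule, the 10 highest fold changes included the lipid transfer protein genes LTP4 (10.25 ± 0.87) and LTP3 (8.52) and TSPO (9.15), and the 10 lowest included the germin-like gene GER1 (-7.42 ± 0.24) and PCC1 (-7.09). Within scan day 2, which held 1 wild-type control array, LTP4 was at 12.81, LTP3 at 9.16, TSPO at 7.94, GER1 at -7.495 and PCC1 at -4.43. In all, 11737 of 18307 genes were called, 5627 higher and 6110 lower, and 6149 changed at least 2-fold. At the preset correlation 20 of the 28 lists were called. Not called were proline genes, circadian clock genes (median -0.20, 6 higher and 8 lower of 20), jasmonate genes (median -0.001, 7 higher and 8 lower of 27), clathrin and endocytosis (0.24, 7 higher and 1 lower of 14), iron homeostasis (-0.21, 2 higher and 2 lower of 9), cuticle and lipid transfer proteins (0.52, 10 higher and 5 lower of 17), root cell type markers (-0.56, 2 higher and 7 lower of 18) and the AFL1 family. Counts adjusted over the list alone were the same except for ER bodies and aquaporins, with 14 lower members each. With genes not above background in a group set at their bounds, the medians were 1.83 for ABA synthesis, 3.80 for clade A phosphatases, 1.98 for flavonoids, -1.21 for auxin response and -0.97 for shoot markers, and those of the other called lists were as given. The clock list had a mean of 0.09, opposite in sign to its median.

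With an estimated inter-gene correlation 5 list calls held in wild type: ABA synthesis (adjusted p = 0.018), clade A phosphatases (0.00258), dehydration proteins (0.014), expansins (0.00498) and heat shock proteins (0.018). The other 15 lost the call. Within slide 2, which held an array of each wild-type treatment, 8709 genes were called with the slide as a block and 19 of these lists, all but ER folding, were called. Median centring gave 6786 higher and 5135 lower genes, with a median shift of all genes of 0.13, against 5627 and 6110.

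**Figure D1:**
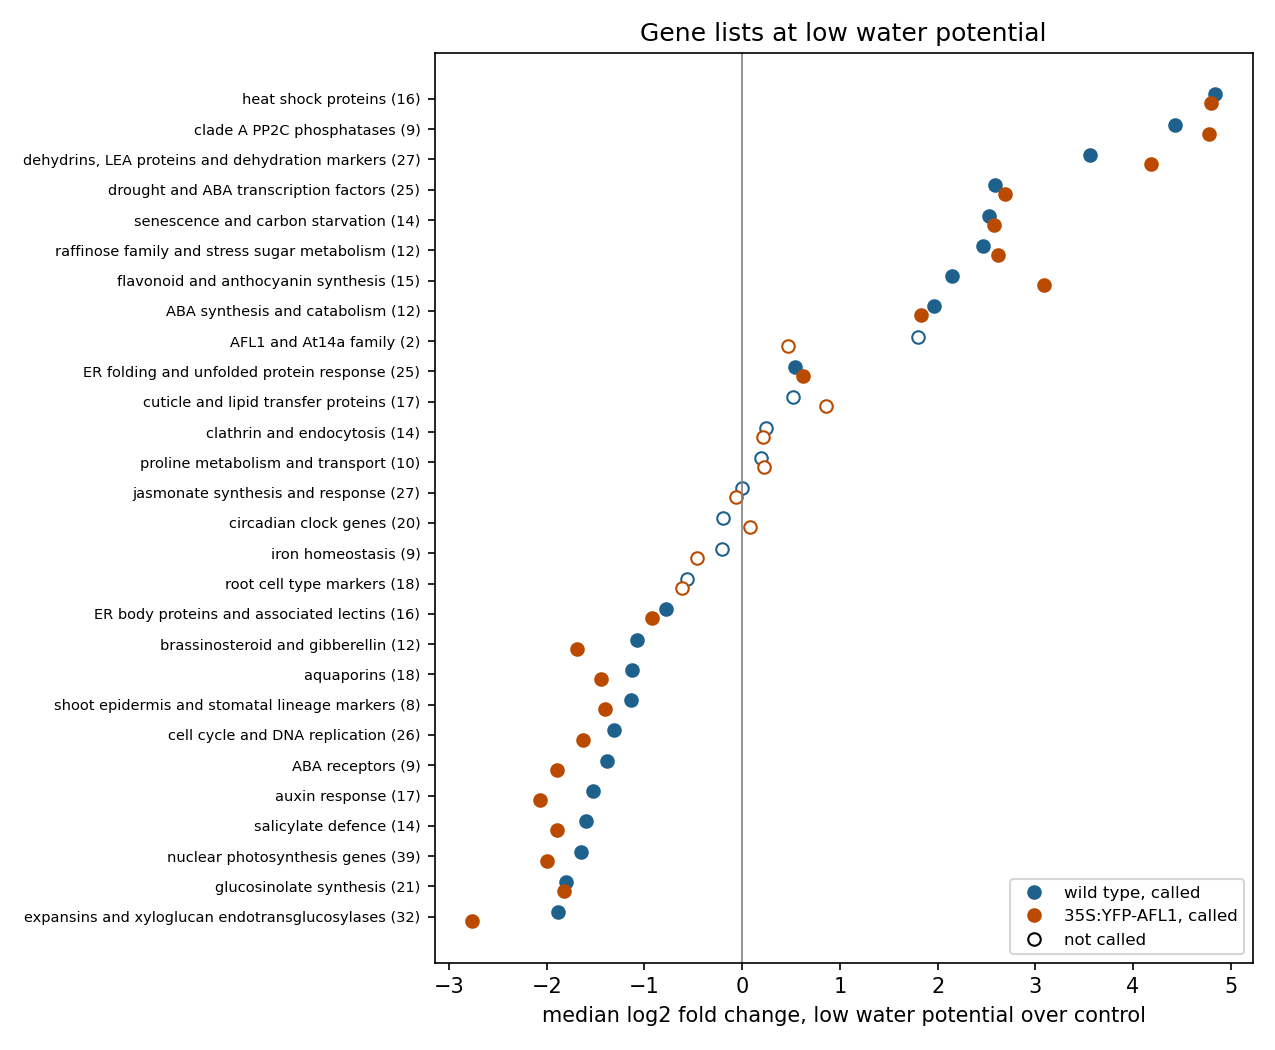
Median log2 fold change (low water potential over control, horizontal axis) of each gene list (vertical axis, number of measured members in brackets) in wild type (blue, n = 4 and 4 arrays) and 35S:YFP-AFL1 (orange, n = 3 and 3); filled points were called at the preset correlation. Medians ran from -1.89 for expansins to 4.84 for heat shock proteins in wild type, and from -2.76 to 4.79 in 35S:YFP-AFL1.

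The second comparison asked for the same response in 35S:YFP-AFL1. It had the same outline, with 11592 genes called, 5502 higher and 6090 lower, and 6856 changed at least 2-fold. All 27 dehydration proteins (median 4.19), all 9 clade A phosphatases (4.78) and all 16 heat shock proteins (4.79) rose, and NCED3 rose by 7.60 ± 0.26 (SE, n = 3 and 3). All 39 photosynthesis genes fell (median -1.998, adjusted p = 0.138 with an estimated correlation), with LHCB2.3 at -8.44 (-2.68 with the slide as a block). Expansins and xyloglucan endotransglucosylases fell in 25 of 32 cases and rose in 1 (median -2.76), with XTH9 at -5.35, and the cell cycle list had 24 of 26 members lower (median -1.63, adjusted p = 0.05 with an estimated correlation). P5CS1 rose by 4.41 and PAD4 fell by 5.17. Flavonoid genes rose in 14 of 15 cases (median 3.09, adjusted p = 0.145 with an estimated correlation), with PAP1 at 4.74. With the slide as a block their median was 1.80, below the blocked 2.41 of wild type. LTP4 was at least 1710-fold higher, and GER1 changed by -8.87.

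In 35S:YFP-AFL1 the same 20 lists were called as in wild type. The median of ABA synthesis was 1.83. Of the lists that rose but lost the call with an estimated correlation, the medians were 2.69 for drought transcription factors, 2.61 for raffinose metabolism, 2.58 for senescence and 0.62 for ER folding. Their adjusted p with an estimated correlation was 0.0858, 0.0858, 0.149 and 0.475. Of those that fell and lost it, the medians were -1.89 for ABA receptors, -1.83 for glucosinolates, -2.07 for auxin response, -1.69 for brassinosteroids, -1.44 for aquaporins, -1.90 for salicylate defence, -0.93 for ER bodies and -1.41 for shoot markers. Their adjusted p with an estimated correlation was, in the same order, 0.05, 0.149, 0.05, 0.135, 0.0561, 0.249, 0.196 and 0.0858. The uncalled lists had medians of 0.23 for proline, 0.47 for the AFL1 family, 0.21 for endocytosis, -0.06 for jasmonate, 0.08 for the clock, -0.61 for root markers, -0.47 for iron homeostasis and 0.86 for cuticle genes. The means of the jasmonate list (0.42) and of the clock list (-0.06) were opposite in sign to the medians. With genes at their bounds the medians became 0.98 for ABA synthesis, 3.68 for clade A phosphatases, 1.82 for drought transcription factors, 2.24 for raffinose metabolism, 2.28 for flavonoids, -1.88 for ABA receptors, -1.56 for the cell cycle, -1.55 for auxin response, -1.18 for brassinosteroids, -2.46 for expansins and -1.27 for shoot markers. With an estimated correlation 5 calls held, with adjusted p = 0.0361 for ABA synthesis, 0.00242 for clade A phosphatases and for expansins, 0.0133 for dehydration proteins and 0.0236 for heat shock proteins. Counts adjusted over the list alone were the same except for aquaporins, with 3 higher in place of 2. With the slide as a block 6565 genes were called, ER folding lost its call (adjusted p = 0.704) and cuticle genes gained one (adjusted p = 0.0421). Median centring gave 6993 higher and 5035 lower genes with a shift of 0.17.

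The responses of the genotypes correlated across genes at r = 0.959, with a regression slope of 1.08 for 35S:YFP-AFL1 on wild type; genes are not independent replicates. Both genotypes called 10119 genes in the same direction and 3 in opposite directions, where independent lists would share 3724 in the same direction. Of the wild-type calls, 86.2% were called in the same direction in 35S:YFP-AFL1. No slide held 35S:YFP-AFL1 arrays of both treatments, so that no correlation within slides could be had. With the slide as a block it was 0.953, but both blocked responses contain the difference of the same slide 2 arrays and correlate by construction.

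The AFL1 transcript was examined first among the genotype differences. Its probes rose in wild type as well, which carries no transgene, so that their signal includes the endogenous transcript, and whether they also detect the transgene's transcript was not tested. On the log2 scale relative to the 75th percentile, AFL1 was 2.45, 2.51 and 2.08 in the unstressed 35S:YFP-AFL1 arrays, against 0.66, 0.04, -0.41 and -0.55 in unstressed wild type. The log2 fold change was 2.41 (95% confidence interval 1.84 to 2.98, adjusted p = 0.00453), and every 35S:YFP-AFL1 array lay above every wild-type array. The other probes of AFL1 gave 1.89 and 2.03. Within slide 4 it was 1.68 against 1 wild-type array, with an adjusted p of 0.112. At low water potential AFL1 itself rose by 3.73 ± 0.24 in wild type (adjusted p = 2.12e-08) and by 1.64 ± 0.28 in 35S:YFP-AFL1 (adjusted p = 0.000192). The genotypes then differed by 0.32 (interval -0.25 to 0.88, adjusted p = 0.526), while the other probes gave -0.238 and 0.256. The difference of the responses was -2.09 (interval -2.89 to -1.29), with an unadjusted limma p of 8.19e-05 and an adjusted p of 0.155. The other probes gave -2.125 and -1.771 for it. Within scan day 2, which held 1 wild-type control array, the difference of the responses was -1.326. On a linear scale in units of the 75th percentile, AFL1 was 1.01 ± 0.408 (SD, n = 4) in wild type and 5.12 ± 0.796 (SD, n = 3) in 35S:YFP-AFL1 without stress, and 12.9 ± 3.05 and 15.9 ± 1.5 with stress, which are differences of 4.11 and 2.91. Against the wild-type array of the same slide the differences were 3.54 and 4.8, so that their order turned. AT14A, the related gene of the family list, was not called between genotypes in control (0.02, adjusted p = 0.983) or at low water potential (-0.55, interval -1.04 to -0.06, adjusted p = 0.201). Its change at low water potential was -0.12 in wild type and -0.69 in 35S:YFP-AFL1 (adjusted p = 0.0235), and the latter was 0.32 with the slide as a block.

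**Figure D2:**
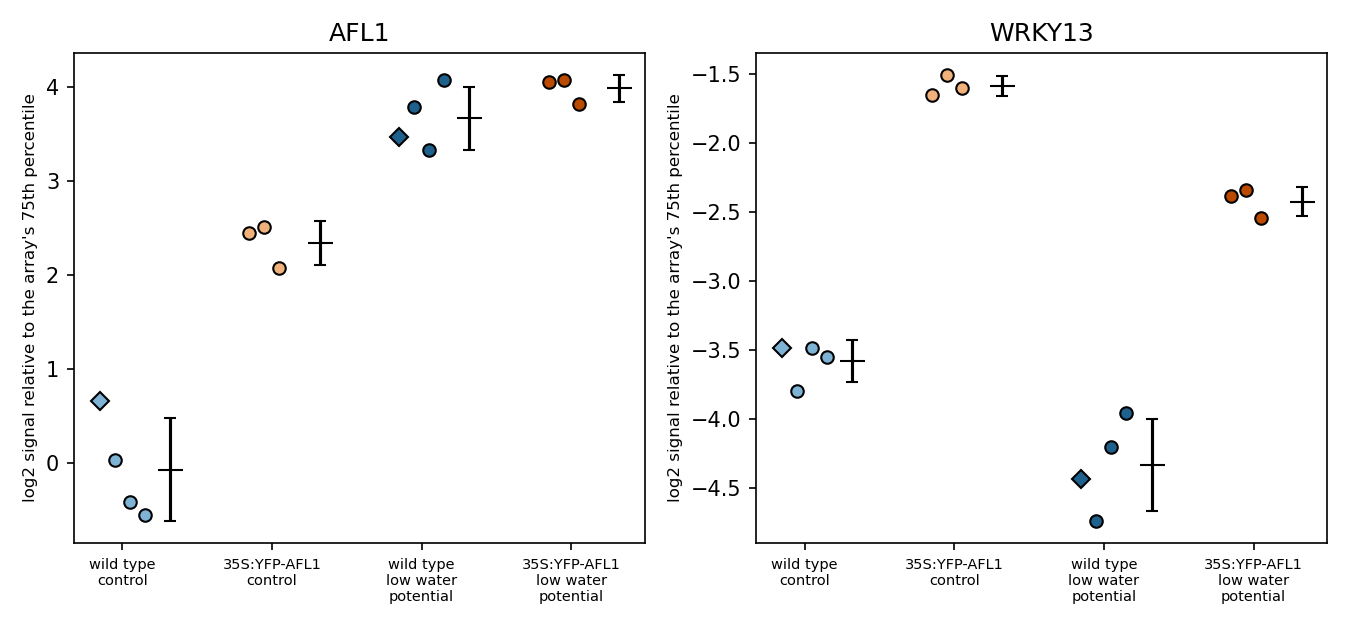
Signal of AFL1 and WRKY13 (log2 relative to the array's 75th percentile, vertical axis) in each array by group (horizontal axis), with the group mean and SD beside the points; diamonds mark wild-type replicate 1, which shared a slide with the 35S:YFP-AFL1 arrays. WRKY13 lay between -1.66 and -1.51 in unstressed 35S:YFP-AFL1 and between -3.80 and -3.48 in unstressed wild type.

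In unstressed seedlings 4 of 18307 genes were called between the genotypes. AFL1 and WRKY13, a WRKY transcription factor gene, were higher, with WRKY13 (AT4G39410) at 1.99 ± 0.16 (SE, n = 3 and 4, adjusted p = 0.000303). BGLU17 (AT2G44480), a beta-glucosidase gene, was called lower but was not well above background in 35S:YFP-AFL1 and is bounded only at 1.05-fold. AT2G21100, named after its value was seen, was lower by -1.63 (adjusted p = 0.0241). With the slide as a block WRKY13 was at 1.90 (adjusted p = 0.00555) and AT2G21100 at -1.25 (adjusted p = 0.194), and BGLU17 lost its call (adjusted p = 0.184). Leaving out wild-type control replicate 1, the array that shared slide 4, raised the count from 4 to 536, and the block of slides gave 34. The count was 2 without wild-type control replicate 2 or 35S:YFP-AFL1 control replicate 3, 22 without 35S:YFP-AFL1 control replicate 1, and 9 and 23 without wild-type stress replicates 1 and 3. No list was called with an estimated correlation.

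At the preset correlation 8 lists were called in unstressed seedlings. Lower were jasmonate genes (median -0.60), root cell type markers (-0.57), salicylate defence (-0.56), drought transcription factors (-0.24), dehydration proteins (-0.23) and ER bodies (-0.20). Higher were the AFL1 family (1.21, from AFL1 alone) and the cell cycle list (0.24). Apart from AFL1, no member of these lists was called over all genes. Adjusted over the list alone, 10 jasmonate genes were lower and 1 higher, and 7 root markers and 4 genes each of the drought and dehydration lists were lower. The adjusted p with an estimated correlation was 0.312 for all of these but ER bodies (0.353). Within slide 4 the jasmonate list lost its call (adjusted p = 0.927), as did the drought (0.999), dehydration (0.431), salicylate (0.927) and AFL1 family (0.55) lists. Root markers had a median of -0.62 (adjusted p = 0.000604) there, and ER bodies (0.000604) and the cell cycle (0.000732) stayed past the threshold. The heat shock list, not called over all arrays (0.16), had a median of -0.39 within slide 4. The 1 wild-type array there had a list mean of -2.75, against -3.48 to -3.06 in the other wild-type control arrays. With genes at their bounds the medians were -0.19 for drought transcription factors and -0.22 for dehydration proteins. A list of 27 rapid touch and wound response genes was written after the genotype differences had been seen. Its 25 measured genes had a median of -1.01 over all arrays and 1.04 within slide 4. Of these, 0 were called, also when adjusted over the list alone. The unadjusted p of camera was 0.304 with an estimated correlation.

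At low water potential 397 genes differed between the genotypes, 87 higher and 310 lower in 35S:YFP-AFL1, and 229 of the lower genes were at least 2-fold lower. WRKY13 was again higher, by at least 3.33-fold (adjusted p = 0.000503), and was not well above background in wild type. EARLI1 and AZI1, which encode related hybrid proline-rich proteins of the lipid transfer family, were at least 2.46-fold and 1.99-fold higher. LOX2, a lipoxygenase gene of jasmonate synthesis, was higher by 1.25 ± 0.27 (SE, n = 3 and 4), the acetyltransferase gene NATA1 by 1.88, the clock-associated gene BOA by 1.36 and the anthocyanin gene UF3GT by 1.21. Lower were ORA47, an ERF transcription factor gene of the jasmonate response, by at least 14.8-fold, BAP1 by at least 3.86-fold, and the U-box ubiquitin ligase gene PUB22, at -3.04. The purple acid phosphatase gene PAP7 was at -2.95, the thalianol synthase gene THAS1 at -2.63, and RHS13, a root hair gene, and CYP81F2, of indole glucosinolate modification, were at least 2.56-fold and 2.75-fold lower. Of the genes named here and in the gene groups of this comparison, WRKY13 and ORA47 were called within slide 5 and the others were not; there LOX2 was at 1.47 (adjusted p = 0.105), NATA1 at 1.82 (0.267) and PUB22 at -1.38 (0.311).

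**Figure D3:**
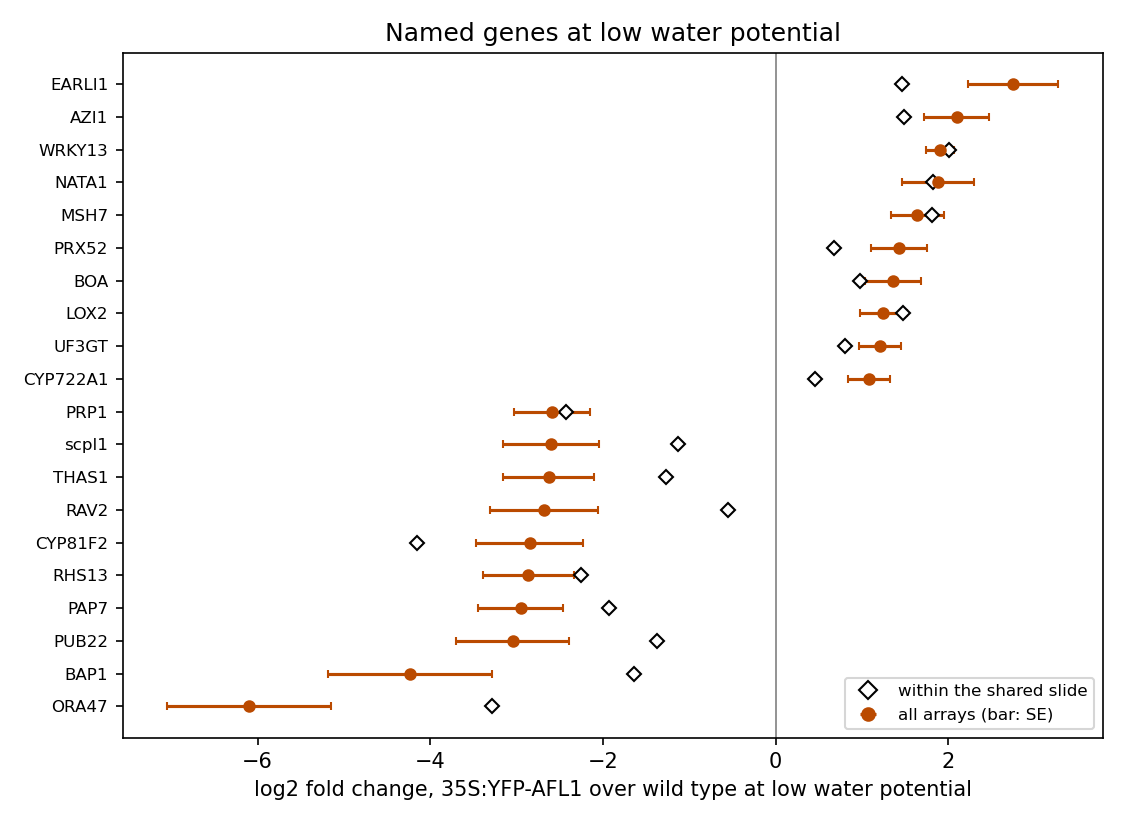
Log2 fold change of 35S:YFP-AFL1 over wild type at low water potential (horizontal axis) for the 10 highest and 10 lowest named genes (vertical axis), over all arrays (orange, bar SE, n = 3 and 4) and within slide 5 (diamonds, 3 arrays against 1). ORA47 was at -6.10 over all arrays and -3.28 within the slide, and WRKY13 was at 1.91 and 2.01; fitted values of genes not well above background are not bounds.

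Of the gene groups at low water potential, expansins and xyloglucan endotransglucosylases were lower in 35S:YFP-AFL1, with 7 of 32 members lower and none higher (median -0.57). This was the list whose call held with an estimated correlation (adjusted p = 0.00693), and within slide 5, against 1 wild-type array, its median was -0.45 (adjusted p = 0.0013 at the preset correlation). EXPA11 was at least 2.32-fold lower, EXPA8 at least 1.71-fold and XTH15 at -1.56, and 14 members were lower adjusted over the list alone. Root cell type markers were lower (median -0.42), with 5 of 18 called: CASP1 at -1.46, MYB36 at -1.22 and PRP3 at -2.03, with CASP5 at least 2.18-fold lower. ER bodies were lower (median -0.35, 3 of 16 called), with the beta-glucosidase genes BGLU22 at -1.52 and BGLU21 at -0.82. Photosynthesis genes were lower (median -0.51, 2 of 39 called), with LHCB2.2 at -1.47, as was salicylate defence (-0.75, 1 of 14 called), with PAD4 at -0.98. Flavonoid genes were higher (0.61, 1 of 15 called), and heat shock proteins were higher (0.53, none of 16 called). Adjusted over the list alone, 15 photosynthesis genes, 5 of ER bodies, 8 root markers and 1 of salicylate defence were lower, and 4 flavonoid genes, 2 heat shock genes and 1 root marker, CASP2, were higher. For these 6 lists the adjusted p with an estimated correlation was 0.373 for root markers, ER bodies, salicylate defence and heat shock proteins, 0.428 for photosynthesis and 0.517 for flavonoids. Shoot epidermis markers were not called, with a median of 0.10, or -0.02 with genes at their bounds. With genes at their bounds the expansin median was -0.56 and the salicylate median -0.50.

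Single arrays decided the size of the genotype difference at low water potential. The count of 397 became 3523 without wild-type stress replicate 1, 12, 48 and 226 without 35S:YFP-AFL1 stress replicates 3, 2 and 1, 157 and 154 without wild-type stress replicates 2 and 3, 263 without wild-type control replicate 3, and 1 when the spread was taken from the stress arrays alone. With the slide as a block 62 genes were called, and 7 of the 310 lower and 3 of the 87 higher genes were among them, ORA47 (adjusted p = 0.0213) and WRKY13 (0.00594) included. The arrays of slide 5 were among those that called the 397 genes, so that their signs and sizes within that slide are no separate test. Of the 3523 genes called without wild-type stress replicate 1, 51.9% had the same sign within slide 5, and the median ratio of the fold change there to that against the other wild-type arrays was 0.02. Within slide 5 the photosynthesis list had a median of 0.04. ER bodies (median -0.56) and heat shock proteins (0.368) stayed past the threshold there, against 1 wild-type array. Root markers, salicylate defence and flavonoids did not. The root marker median was -0.356 there against -0.415 over all arrays, so that it changed little. The medians were -0.367 against -0.746 for salicylate defence and 0.204 against 0.608 for flavonoids. Lists called there but not over all arrays were ER folding (median -0.26), glucosinolates (-0.36) and the cell cycle (-0.30), which were lower, and senescence (0.19) and jasmonate genes (0.18), which were higher. These rest on wild-type stress replicate 1. Its mean was 1.74 for ER folding (other wild-type stress arrays 1.24 to 1.34) and -0.725 for glucosinolates (-1.5 to -1.21). For senescence it was 1.85 (2.9 to 3.24) and for jasmonate genes -0.932 (-0.278 to 0.29). For the cell cycle another array, replicate 4, lay farthest from the rest. The touch and wound response genes had a median of -2.07 over all arrays and 0.07 within slide 5 in this comparison. Of the 25 measured, 0 were called over all genes and 15 were lower when adjusted over the list alone. The unadjusted p of camera was 0.155 with an estimated correlation. Normexp correction with quantile normalization gave 153 higher and 216 lower genes in place of 87 and 310.

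**Figure D4:**
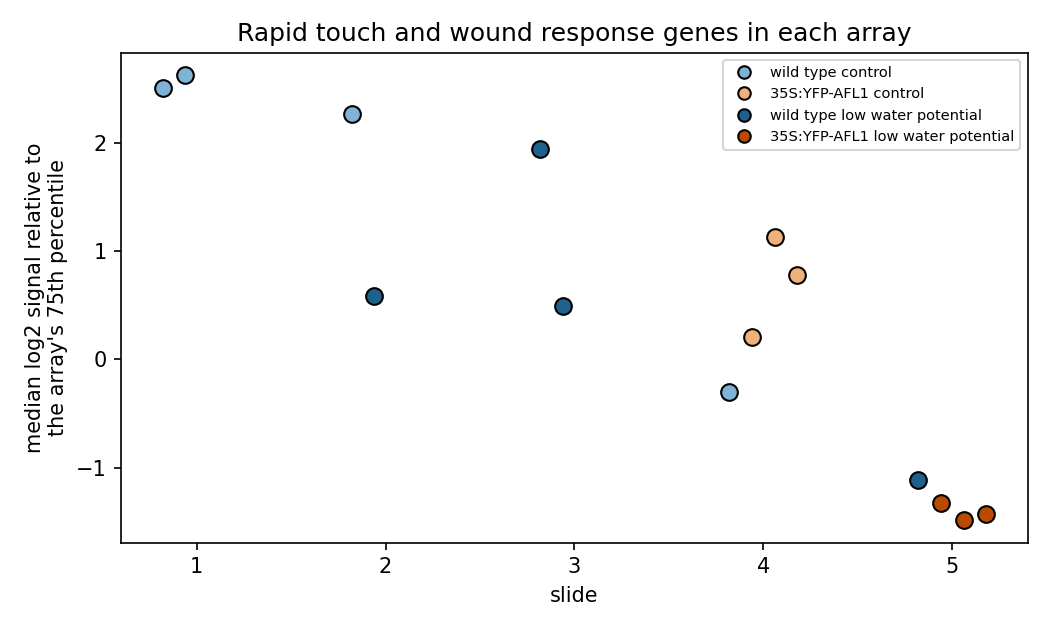
Median signal of the 25 measured touch and wound response genes (log2 relative to the array's 75th percentile, vertical axis) in each array by slide (horizontal axis), by genotype and treatment. Wild-type control replicate 1 was at -0.30 and the other wild-type control arrays at 2.27 to 2.63; wild-type stress replicate 1 was at -1.11, the other wild-type stress arrays at 0.49 to 1.94, and the 35S:YFP-AFL1 stress arrays at -1.49 to -1.33.

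The test of the difference between the stress responses called 0 genes with limma, where 1782 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0839. The count was 20 with the slide as a block, 754 without wild-type stress replicate 1, 43 without wild-type control replicate 1, 1 without 35S:YFP-AFL1 stress replicate 1 and 1236 with array weights. Of the lists, 11 were called at the preset correlation. Expansins and xyloglucan endotransglucosylases fell further at low water potential in 35S:YFP-AFL1 (median difference -0.38), and theirs was the call that held with an estimated correlation (adjusted p = 0.0489). The adjusted p with an estimated correlation was 0.207 for the cell cycle list, whose median difference was -0.38, and ran up to 0.493 for the other lists. The slide block sets 1 wild-type array per treatment against the 35S:YFP-AFL1 arrays. With it the expansin, cell cycle and heat shock lists kept their calls, and ER folding, not among the 11, gained one.

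Of the 4 genes that differed between genotypes without stress, 1 had changed in the same direction at low water potential in wild type and 2 in the opposite direction. These comparisons shared the wild-type control arrays. Independent lists would share 1.28 genes in each direction, and 100 simulations of unchanged groups with shared controls gave a mean of 0.01 and 0. No group changed in the simulations, whereas 11737 genes were called here for the wild-type stress response. Their overlap is therefore no baseline for the observed one. With the control arrays split between the comparisons, the mean over 6 splits was 6.33 genes in the same direction (range 0 to 32) and 28.7 in opposite directions (range 1 to 162). The covariance of the fold changes was -0.0505, against 0.0339 in the simulations, which likewise held no stress response. Leaving out wild-type control replicate 1, the only wild-type array on slide 4, raised the overlap to 389 genes. The overlap thus depends on 1 array and does not show that the genotype opposes the stress response. The genotype differences of the 2 treatments, which shared no array, correlated across genes at 0.454, and at 0.195 within slides.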

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

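Of the tests in this part, those of a difference between slides and of a neighbouring enhancer for WRKY13, of an equal fall and of slides for the root markers, and of a mislabelled sample were chosen only after the result was seen. The list of touch and wound genes was written after the genotype differences had been seen but without the values of its genes.

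Genes were lower in 35S:YFP-AFL1 than in wild type at low water potential (310 of the 397 called), and wild-type replicate 1 is the only wild-type array on their slide. The WRKY13 signal of replicate 1 was -4.438, within the -4.74 to -3.96 of the other wild-type stress arrays. The 35S:YFP-AFL1 stress arrays lay at -2.55 to -2.34. The rule that named WRKY13 at low water potential used this array, so that its naming there is no test. WRKY13 was also called in unstressed seedlings, where this array is in neither group. On that basis the signal argues against a mislabelled replicate 1, but it is 1 gene, not well above background in wild type. A difference between slides may contribute. Of the 3523 genes called without replicate 1, the median ratio of the fold change within slide 5 to that against the other arrays was 0.02, or 0.06 for the 1993 lower ones. The same sign was kept by 51.9% of the 3523. How many of the 310 are among them was not counted. All 310 kept their sign within slide 5, with a median of -0.995 against -1.347 over all arrays. The arrays of slide 5 had helped to call the 310, so that this is no separate test. A touch or wound response that was stronger in the wild-type stress seedlings of the other slides may contribute, as the median of that list, which holds none of the genes named for this comparison, was -2.071 over all arrays and 0.07 within slide 5, with an unadjusted p of 0.155 with an estimated correlation; 0 of its 25 genes were among the 397 and 18 were lower without replicate 1. An effect of AFL1 stays open for the 7 lower genes called with the slide as a block, which rests on 1 wild-type array, and for the others genotype and slide could not be separated.

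Root cell type markers were lower in 35S:YFP-AFL1, with medians of -0.57 in control and -0.42 at low water potential. Within slide 4 the control median was -0.62 (camera adjusted p = 0.000604 at the preset correlation), and within slide 5 the median was -0.36 (adjusted p = 0.13). Each value rests on 1 wild-type array, and no test within slides used an estimated correlation. They thus do not decide on a difference between slides alone. With an estimated correlation the list was called in neither treatment over all arrays (adjusted p = 0.312 and 0.373). The median of 14 markers outside hairs lay -0.143 from that of 4 hair markers (exact two-sided permutation p = 0.982), which decides nothing for or against a lower share of root in the harvested seedlings. The 8 endodermal markers lay -0.783 from the 10 others over all arrays (exact two-sided permutation p = 0.0525 over 43758 splits), and within slides at -1.05 against -0.30 in control and -0.543 against -0.356 at low water potential, but this set was picked after some of its genes were seen to be lower, so that the comparison decides neither an equal fall of all root cell types nor a lower share of root. A lower share of root, an effect of AFL1 on root cells and a difference between slides stay open.

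WRKY13 was higher in 35S:YFP-AFL1 in both treatments. A change of the whole chromosomal segment is argued against by the 10 nearest measured genes, whose median was 0.12 with a median absolute deviation of 0.199. The smaller of the changes within slides was 1.897, each against 1 wild-type array. The rule that named WRKY13 in a treatment used the arrays of that slide, so that the sign there is no separate test. The slide 5 arrays were in neither group of the call without stress. Among them WRKY13 was -4.438 in wild type and -2.55 to -2.34 in 35S:YFP-AFL1. This goes against a difference between slides alone, but rests on 1 wild-type array where the gene was not well above background. An enhancer effect of a transgene inserted nearby stays open, since the neighbour AT4G39420 changed by 0.258 and 0.99 within slides and by 1.14 and 1.35 over all arrays (adjusted p = 0.235 and 0.0686). An effect of the AFL1 protein stays open as well, as does any difference between seed stocks, neither of which was tested.

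Other groupings of the same arrays were counted for each comparison. For the wild-type stress response 1 of 35 splits, the real one, gave as many as 11737 genes, with 142 as the highest of the others. That share is under 0.05 but is the smallest that 35 splits can give, so that by itself it does not exclude chance. The other splits mix the treatments, which puts the treatment effect into their spread and lowers their counts. The response of 35S:YFP-AFL1 shared no array with that of wild type and correlated with it at 0.959. Both called 10119 genes in the same direction and 3 in opposite directions, which argues against chance for the wild-type response. For 35S:YFP-AFL1 the 10 splits of 3 against 3 are too few for a share under 0.05, with 11592 genes in the real split (the 1 as large) and 0 as the highest other. For the genotype difference without stress 2 of 35 splits gave as many as 4 genes, so that chance is not excluded; the other was the split of wild-type replicates 2 to 4 from the arrays of slide 4, with 732 genes. At low water potential 2 of 35 gave as many as 397, and the other was the split of wild-type replicates 2 to 4 from the arrays of slide 5, with 4041 genes. Both splits follow the slides and call far more genes than the real ones, which points to a structure of the samples by slide or by something that goes with it. The split without stress also follows the scan days, so that slide and scan day cannot be told apart there. The split at low water potential does not follow the scan days. For the difference of the responses all 100 drawn reassignments gave as many as 0, and the highest gave 1886.

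Several arrays stood apart from their group, by a gap that chance gives in about 1 of 20 tests. Over 35 measures in both wild-type groups, 8 of 70 tests passed, against 3.5 by chance, and 4 of the 8 fell on wild-type replicate 1 of either treatment. Wild-type control replicate 1 had a second component score of 21.9 (the others -28.2 to -22.4) and a mean of the touch and wound genes of -0.754 (the others 1.80 to 2.22). Wild-type stress replicate 1 had a mean of ABA synthesis genes of -0.0428 (0.315 to 0.352) and of photosynthesis genes of 4.12 (4.87 to 5). The ER folding mean of wild-type control replicate 2 was 1.03 (0.944 to 0.957), and the cell cycle mean of wild-type control replicate 4 was -0.592 (-0.775 to -0.746). The aquaporin mean of wild-type stress replicate 4 was 2.51 (2.27 to 2.29), and the iron homeostasis mean of wild-type stress replicate 3 was 0.044 (-0.439 to -0.357).

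The stress responses of the genotypes differed in 11 lists by the test of the difference, at the preset correlation. The median log2 difference, 35S:YFP-AFL1 minus wild type, was -0.567 for ABA receptors, 0.415 for dehydration proteins, -0.414 for photosynthesis, -1.331 for the AFL1 family, 0.412 for jasmonate, 0.611 for flavonoids, -0.385 for the cell cycle, -0.346 for auxin response, -0.382 for expansins, 0.398 for heat shock proteins and 0.257 for cuticle genes. With the slide as a block 3 of the 11 kept their direction and call, 5 lost the call and 3 reversed. With an estimated correlation expansins kept the call, and the adjusted p of the other 10 ran from 0.207 to 0.493.

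Of the probes matched to no gene, which the comparisons do not use, 1852 of 3347 tested (55.3%) changed at low water potential in wild type and 1925 in 35S:YFP-AFL1.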

How the results depend on the processing

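Alternatives that leave out both wild-type replicates 1, use only slides 4 and 5 or 1 scan day, or keep all probes were chosen after seeing the data. The wild-type stress count, between 11030 and 12072 with an array left out, and the 35S:YFP-AFL1 stress count, between 10592 and 12226, changed by more than 1.5 times only in the settings named for them here. Genotype counts depended on single arrays and on how slides were handled. Stricter thresholds lower a count by construction; for the other changes the cause was not tested. Of the values of named genes under alternatives, 3660 of 3693 kept direction and side of the threshold for wild-type stress, 3542 of 3576 for 35S:YFP-AFL1 stress, 129 of 176 for genotype without stress (31 lost the call, 2 gained it), 728 of 1234 for genotype with stress (497 lost, 7 gained) and 51 of 58 for the difference. For lists it was 588 of 600, 571 of 580, 210 of 232, 188 of 203 and 270 of 308. These shares pool unlike settings, and 98 of the 203 came from leaving out 1 array. With the slide as a block, which rests on 1 wild-type array per slide, 3 of 8 lists kept both without stress. It was 3 of 7 with stress and 3 of 11 for the difference. Of 42 named-gene values for genotype with stress, 7 kept both with the slide as a random block and 4 with only the groups compared. Signal over background limits genes that are dim in a group.

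Leaving out each array gave 2 to 536 genes for genotype without stress (536 without wild-type control replicate 1), 12 to 3523 with stress (12, 48 and 226 without 35S:YFP-AFL1 stress replicates 3, 2 and 1, 3523 without wild-type stress replicate 1) and 0 to 754 for the difference (754 without the latter). The overlap of genotype and stress calls ran from 2 to 389, the correlation of the responses from 0.94 to 0.965, called lists from 63 to 69, and AFL1 from 2.247 to 2.651 without and 0.206 to 0.454 with stress. The main values were 4, 397, 0, an overlap of 3, 0.959, 66 lists, 2.409 and 0.317.

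In the order genotype without stress, genotype with stress and difference, the slide as a block gave 34, 62 and 20 genes, with 6565 for 35S:YFP-AFL1 stress, AFL1 at 1.683 (adjusted p = 0.112), a correlation of 0.953 (both responses then share the slide 2 arrays) and an overlap of 24. Array weights gave 1634, 4158 and 1236, with a correlation of 0.943 and an overlap of 1114. Leaving out both wild-type replicates 1 gave 1399, 4148 and 1173, with 0.939 and 1009. Only slides 4 and 5 gave 51, 64 and 23, with AFL1 at 1.683, 0.942 and an overlap of 44. Only scan day 2 gave 18, 1 and 11, with 7683 for wild-type stress, AFL1 at 1.683 (adjusted p = 0.168), 0.924 and an overlap of 15. Well above background on all arrays gave 1, 187 and 4, with an overlap of 1.

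For genotype without and with stress, the slide as a random block gave 1 and 47, with AFL1 at 2.099 (adjusted p = 0.0578), a correlation of 0.965 and an overlap of 1. The scan day block gave 1 and 252, with AFL1 at 2.106 (adjusted p = 0.237), 0.949 and 1. An adjusted p under 0.01 gave 2 and 32. Quantile normalization gave 7 without stress and an overlap of 7. No filter on dim probes gave 237 with stress and a correlation of 0.926. Only the groups compared gave 1 with stress and AFL1 at 2.409 without (adjusted p = 0.0854). A 2-fold threshold gave 6149, 6856 and 254 for the stress responses and genotype with stress. All probes gave 18003 and 17825 for the stress responses and 9 for genotype without stress. The correlation over wild-type calls was 0.973, split controls gave a mean overlap of 35.03, and an estimated correlation called 12 lists. Over its alternatives the adjusted p of AFL1 without stress ran from 8.83e-05 (array weights) to 0.237.

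The labels do not say that replicate numbers pair the arrays. Deviations from the group mean of 19 same-numbered pairs correlated at -0.117 to 0.397, over 0.1 in 6 of them, and 6 of 14 arrays correlated best with an array of their own number, so that the numbers were not taken as pairs. The replicate block gave 2 and 199 genes for genotype without and with stress.

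These values reversed in direction. AT14A between genotypes without stress was -0.058 with normexp, -0.012 with quantile normalization and with median centring, -0.149 with the slide as a random block, -0.089 with the scan day block, and -0.34 with the slide block, slides 4 and 5 alone and scan day 2 alone. It was -0.02 and -0.092 without wild-type control replicates 2 and 3 and -0.03 without 35S:YFP-AFL1 control replicate 1, in a range of -0.092 to 0.137 with an array left out. AT14A in wild-type stress was 0.038 with median centring, 0.126 with array weights, 0.078 without wild-type stress replicate 1 (range with an array left out -0.232 to 0.078), 0.197 without both replicates 1 and 0.141 on scan day 1. With the slide block it was 0.324 in 35S:YFP-AFL1 stress, and COL2 there was 0.339. With the slide block and on slides 4 and 5 alone, AT14A was 0.047 between genotypes with stress and 0.387 for the difference. In both settings and on scan day 2, without stress, ORA47 was 0.395, drought transcription factors 0.013 and salicylate defence 0.071. In both settings photosynthesis was 0.043 with stress and 0.103 for the difference, auxin response 0.032 and cuticle genes -0.008 for the difference. On scan day 2 PRR9 in wild-type stress was -0.472 and the jasmonate list -0.57 for the difference.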

Other observations

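Members of lists with no call as a whole changed at low water potential in wild type. In the jasmonate list CORI3 changed by 3.78 and VSP2, a vegetative storage protein gene, by 2.69, while LOX2 changed by -3.08. Among cuticle genes CER1, of wax alkane synthesis, changed by 3.42 and KCS2, a fatty acid elongase gene, by 5.42. The clock gene CCA1 changed by 2.41 and the ferritin gene FER1 by 2.83. Within scan day 2, which held 1 wild-type control array, CCA1 changed by 1.39, FER1 by 2.61 and VSP2 by 4.08. In 35S:YFP-AFL1 the ERF transcription factor gene RAP2.6 was at least 146-fold higher and MYB90, an anthocyanin regulator, at least 55.9-fold higher at low water potential.

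With genotype fitted over both treatments and the slide as a block, a fit chosen after seeing the data, 1 gene of 18307 was called, WRKY13 (adjusted p = 0.000359 from limma). It was higher in 35S:YFP-AFL1, and no fold is given because its probe was not well above background in wild type at low water potential.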
